A study of Homo sapiens with 12 samples.

How the data were processed

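RNA was measured by mRNA sequencing in 2 human gastric adenocarcinoma cell lines, AGS and MKN45. Each line was left untreated or was given 200 nM clofarabine for 48 h, per the labels' protocols, with 3 libraries in each of the 4 groups and 12 libraries in all. Clofarabine is a purine nucleoside analogue that, once phosphorylated in the cell, blocks DNA synthesis and ribonucleotide reductase. AGS cells were grown in F12 medium and MKN45 cells in RPMI medium with more serum, per the labels, so line and medium cannot be separated. RNA was prepared with a column kit and sequenced by a service laboratory on an Illumina NovaSeq instrument, per the labels. The authors deposited 1 table of raw read counts per gene for the whole series, in which no normalization had been applied. Alignment used STAR and the human genome build hg38 (GRCh38), per the submitters' processing notes. The versions, the program that counted reads, its use of strand and any filter are not given in the sources used here.

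The deposited table held counts for 58735 Ensembl genes, and all 58735 had the same identifiers and coordinates as in GENCODE release 29 on GRCh38. Columns were matched to samples by the line, treatment code and replicate number in their names. Totals ran from 15720654 to 27880776 counts per library. Replicates of a group were compared before averaging. In each pair the counts differed by more than sampling noise, with a chi-square per degree of freedom of 1.84 to 4.19, and no pair was identical. The labels do not say whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

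Genes were kept with edgeR's filterByExpr over the 4 groups, which left 16893 genes. Library sizes were scaled with TMM, and CPM values, the counts scaled to library size, use these scaled sizes. The 12 libraries were fitted together with edgeR's quasi-likelihood test (robust), with 1 mean per group, 8 residual degrees of freedom and a common biological coefficient of variation of 0.045. The contrasts tested were clofarabine against untreated in AGS, the same in MKN45, the difference between those effects (AGS minus MKN45), and untreated AGS against untreated MKN45. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. Log2 fold changes carry their standard error (SE), and CPM values are mean ± SD over 3 libraries. Where every library of a group had 0 counts, a fold is given as a lower bound computed against 3 counts over the group, which covers counting error only. It takes the mean of the other group as it stands. The error of that mean is left out, so bounds that rest on few counts are too high as limits.

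The 21 gene lists were fixed before the data were examined: p53 target genes, DNA replication and G1/S genes, G2 and mitosis genes, DNA damage response and repair genes, histone genes, nucleotide metabolism and clofarabine handling genes, PI3K-AKT-mTOR pathway genes, receptor tyrosine kinase genes, cell death genes, interferon-stimulated genes, NF-kB and inflammatory genes, unfolded protein and integrated stress response genes, cholesterol synthesis genes, lysosome and autophagy genes, MYC and ribosome biogenesis genes, gastric and intestinal epithelial genes, epithelial-mesenchymal transition genes, mitochondrially encoded mRNAs, and markers of squamous keratinocytes, of fibroblasts and endothelium, and of blood cells. Each list was tested against the other genes with limma's camera at a preset correlation between genes of 0.01, with adjustment over the 21 lists of a contrast. The same test with an estimated correlation was an alternative, and its adjusted p is given wherever it ended a call. Members were also counted after adjustment over the list alone. Where a list and a gene are described as rising or falling, the adjusted p was under 0.05.

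The genes named were chosen by a rule set before the data were examined. For each treatment comparison these were the 6 largest rises and 6 largest falls among called genes with a symbol, at least 5 CPM in 1 group and treated libraries on 1 side of all untreated ones. To these came up to 2 called members of each list with the smallest adjusted p and at least 1 CPM, and 12 genes in every comparison: CDKN1A, MDM2, GDF15, RRM1, RRM2, RRM2B, DCK, SLC29A1, PIK3CA, PIK3R1, EGFR and MET. For the difference between the lines and for the untreated lines, the 5 largest in each direction were taken. Of the genes picked by this rule 2 are not reported, though they count in the tallies of gene results across alternatives. Genes outside this rule are said to have been chosen after their values were seen.

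The alternatives were DESeq2 size factors, DESeq2's own test, no low-count filter, a stricter filter (10 counts in 3 libraries and 1 CPM), a fit of only the groups compared, the replicate number as a block, a test against a log2 fold change of 1, leaving out each library in turn and, for the lists, camera with an estimated correlation and limma's fry. An offset for each library's trend with transcript GC content was added after seeing the data. The test was checked on simulated counts for 16574 genes with known changes. It recovered 89.3%, 95.7% and 100% of the genes changed by 1.5, 2 and 4 times in AGS, and 74.6%, 91.9% and 100% in MKN45. For the difference between the lines it recovered 63.3%, 83.6% and 95.7%. Of the calls in these simulations, 2.6%, 5.9% and 3.3% were false. Besides p53 targets raised in AGS, 56, 70 and 71 genes were changed by 1.5, 2 and 4 times in AGS. In MKN45 these were 67, 62 and 70 genes. Far more genes were called in the data, and the simulated spread followed expression level only, so these rates need not hold there. Reads shared by near-identical genes could be split by the counting, so values of the AKR1C, SPANX, galectin-7 and histone genes are uncertain, as are those of overlapping and antisense genes, since the use of strand is not stated. Tools were Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.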

Results

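Gene expression was measured in AGS and MKN45, established human gastric adenocarcinoma lines, with and without 200 nM clofarabine for 48 h. The series title names the combination of clofarabine with pictilisib, a PI3K inhibitor, while the 12 libraries cover clofarabine alone. Untreated AGS libraries held 27880776, 16502836 and 18051870 counts, and treated AGS libraries 19546881, 16949658 and 22833617. Untreated MKN45 libraries held 15720654, 16898322 and 22311805 counts, and treated MKN45 libraries 18058940, 22972298 and 16289105. The first principal component of log2 CPM held 86.6% of the variance and separated the lines. The next held 6.58% and separated treated from untreated libraries in both lines. Mitochondrial genes took 3.72% ± 0.06 of counts in untreated and 4.96% ± 0.07 in treated AGS, and 3.40% ± 0.09 and 3.63% ± 0.04 in MKN45 (SD, n = 3).

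The first comparison asked what clofarabine does to AGS cells. Targets of the transcription factor p53 rose and genes of G2 and mitosis fell, the mitosis call ending with an estimated correlation between genes (adjusted p = 0.0758). CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose from 235 ± 6.64 to 1385 ± 79.8 CPM (SD, n = 3), a log2 fold change of 2.56 ± 0.043 (SE). AXL, a receptor tyrosine kinase, rose from 3.67 ± 0.204 to 66.2 ± 9.32 CPM, and MUC13, a transmembrane mucin, from 21.6 ± 0.299 to 166 ± 18.99 CPM. PIK3R1, which encodes the p85 alpha regulatory subunit of PI3K, fell from 176 ± 4.16 to 69.95 ± 6.19 CPM, and SLC7A11, the cystine transporter, from 97.6 ± 4.59 to 7.88 ± 0.328 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4766 of 16893 genes rose and 4571 fell, and 1541 and 462 of them did so by a log2 fold change of at least 1.

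**Figure D1:**
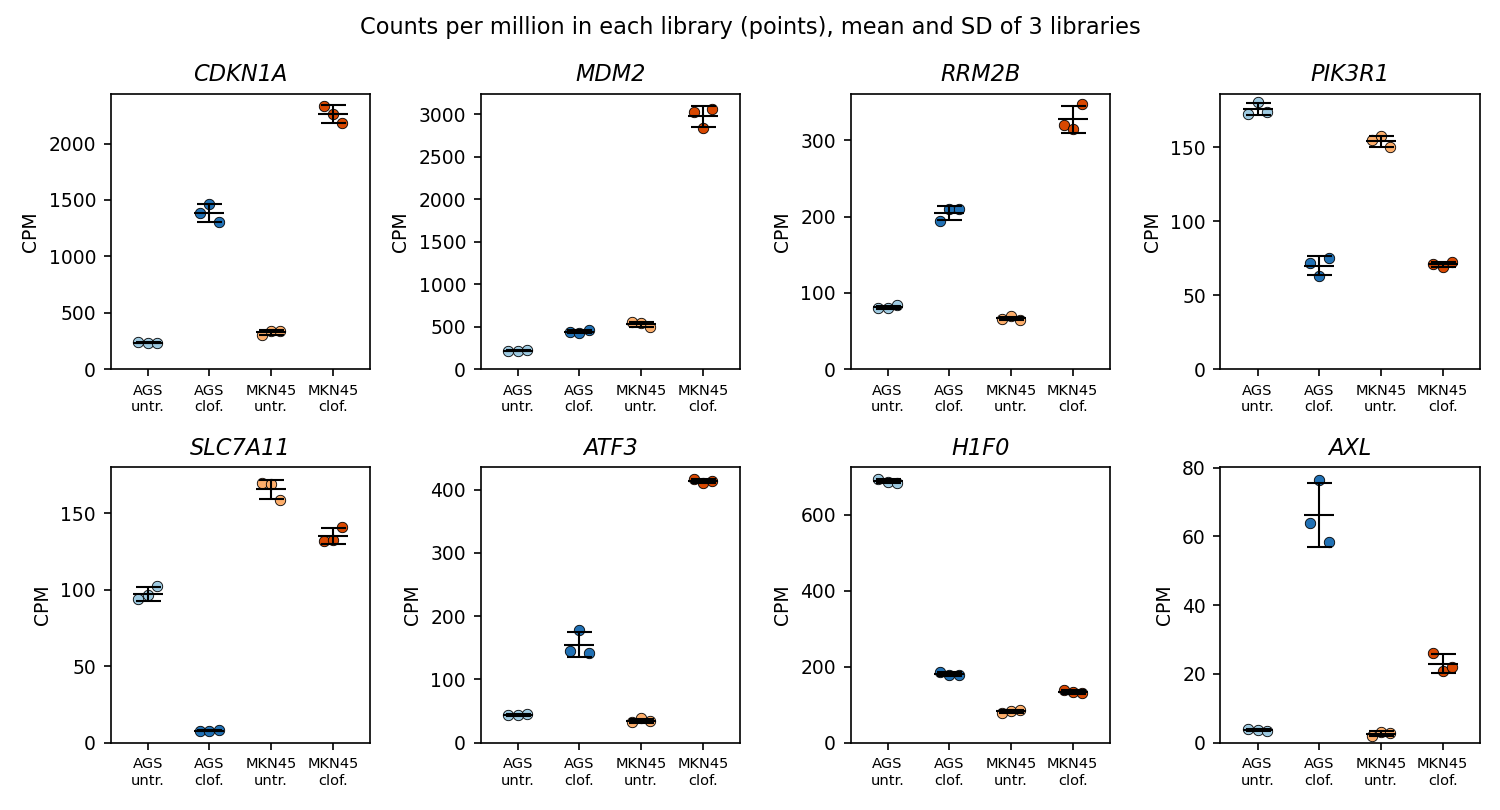
Counts scaled to library size (CPM, linear axes from 0) of 8 genes in each library, with untreated and clofarabine-treated (200 nM, 48 h) AGS and MKN45 on the horizontal axis, points for libraries and bars for the mean ± SD of 3 libraries. CDKN1A averaged 1385 CPM in treated AGS and 2259 CPM in treated MKN45, while H1F0 was lower in treated AGS and higher in treated MKN45.

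The largest rises in AGS began from low levels. UNC13A, a synaptic vesicle priming factor, went from 0.0819 ± 0.0962 to 11.2 ± 2.47 CPM, a log2 fold change of 6.69 ± 0.33 that became 8.22 without untreated AGS replicate 1. SPANXB1, a cancer-testis gene, rose by 5.64 ± 0.34, and LGALS7B, a galectin of squamous epithelia whose reads may be shared with LGALS7, by 5.11 ± 0.48. PTAFR, the platelet-activating factor receptor, rose by 5.11 ± 0.18 to 27.5 ± 6.25 CPM, and DQX1 by 4.88 ± 0.28. CAVIN2, a caveolar protein, rose by 5.00 ± 0.46, or by 4.20 and 6.62 without untreated replicate 1 or 2. The largest falls were those of HTRA3, a serine protease (-4.26 ± 0.36), SLC7A11 (-3.63 ± 0.068) and SPP1, which encodes osteopontin (-3.54 ± 0.18). The aldo-keto reductase genes AKR1C2 (-3.37 ± 0.24) and AKR1C1 (-3.12 ± 0.15) and the adhesion gene NTM (-2.71 ± 0.11) completed them. SLC7A11 (ENSG00000151012) lies on chromosome 4 from 138164097 to 138242349 on the reverse strand, and AXL (ENSG00000167601) on chromosome 19 from 41219203 to 41261766 on the forward strand.

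Of 37 p53 target genes tested in AGS, 35 rose and the other 2 did not pass, with a median log2 fold change of 1.33. Camera's adjusted p was 1.56e-66 at the preset correlation, and 0.00164 with an estimated correlation. BTG2, an antiproliferative gene, rose by 2.20 ± 0.045, MDM2, the ubiquitin ligase of p53, by 1.01 ± 0.041, and GDF15, a secreted stress cytokine, by 2.40 ± 0.095. Among 36 G2 and mitosis genes 30 fell and 2 rose (adjusted p = 5.12e-14, and adjusted p = 0.0758 with an estimated correlation). The spindle gene ASPM fell from 306 ± 8.37 to 156 ± 7.52 CPM and the kinetochore gene CENPF from 579.7 ± 6.05 to 333 ± 19.9 CPM. Of 41 DNA replication and G1/S genes, 21 rose and 11 fell (adjusted p = 0.0792, but 0.0484 without treated AGS replicate 2, 0.0411 with DESeq2 and 0.00988 without a low-count filter). The helicase subunit gene MCM6 fell by 0.97 ± 0.045 on the log2 scale, and CCNE1, which encodes cyclin E1, rose by 1.13 ± 0.053. Among 34 DNA damage response and repair genes, 12 rose and 11 fell (adjusted p = 0.788). The kinase gene WEE1 (-0.62 ± 0.055) and the mismatch repair gene MSH6 (-0.47 ± 0.043) both fell, and the list's median and mean were above 0 while the test pointed down. Histone genes fell in 10 of 14 cases, and the other 4 did not pass (adjusted p = 0.000316). H1F0, the linker histone of non-dividing cells (ENSG00000189060, chromosome 22 from 37805093 to 37807436 on the forward strand), fell from 688 ± 5.75 to 181 ± 4.86 CPM, and HIST1H2BK fell by 0.95 ± 0.11. Small nuclear and nucleolar RNAs, like most histone mRNAs not polyadenylated, stood at 57.5 ± 1.17 CPM in untreated and 49.3 ± 1.89 CPM in treated AGS. A test of such RNA as a source of the histone changes was dropped after its values were seen, so no conclusion is drawn. Adjusted over the list alone, 22 replication genes and 3 mitosis genes rose, and the other counts of this paragraph were the same.

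Of 32 nucleotide metabolism and clofarabine handling genes, 15 rose and 7 fell in AGS (adjusted p = 0.00993, and adjusted p = 0.0804 with an estimated correlation). RRM2B, the p53-inducible subunit of ribonucleotide reductase, rose from 81.2 ± 2.06 to 205 ± 9.29 CPM, and the purine nucleoside phosphorylase gene PNP rose by 1.19 ± 0.045. The other reductase subunits also rose, RRM1 by 0.44 ± 0.041 and RRM2 by 0.98 ± 0.042. SLC29A1, the nucleoside transporter that carries clofarabine into cells, rose by 0.55 ± 0.056. DCK, the kinase that activates clofarabine, had a log2 fold change of -0.004 ± 0.060 (adjusted p = 0.981), which became 0.23 (adjusted p = 0.00048) with the GC content offset. Among 33 PI3K-AKT-mTOR pathway genes 8 rose and 14 fell (adjusted p = 0.18). PIK3R1 (ENSG00000145675, chromosome 5 from 68215720 to 68301821 on the forward strand) fell by 1.32 ± 0.050, and PIK3CA, the catalytic p110 alpha subunit (ENSG00000121879, chromosome 3 from 179148114 to 179240093 on the forward strand), by 0.56 ± 0.082. INPP5D, a lipid phosphatase that acts on the PI3K product, rose by 1.81 ± 0.085. Of 26 receptor tyrosine kinase genes 11 rose and 9 fell (adjusted p = 0.18). AXL rose by 4.16 ± 0.12 and FGFR2 by 1.99 ± 0.061, MET fell by 0.41 ± 0.045, and EGFR had a log2 fold change of 0.018 ± 0.050 (adjusted p = 0.799). When adjusted over the list alone, 8 nucleotide metabolism genes fell, and the other counts of this paragraph were the same.

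Of 32 cell death genes in AGS 16 rose and 3 fell (adjusted p = 0.000778, and adjusted p = 0.08 with an estimated correlation). The pro-apoptotic BAX rose by 1.13 ± 0.043 and BBC3, which encodes PUMA, by 1.79 ± 0.068, and both are also on the p53 list. Interferon-stimulated genes rose in 23 of 38 cases and fell in 2 (adjusted p = 2.54e-05), with OAS1 at 2.21 ± 0.085 and OAS3 at 1.03 ± 0.048, both sensors of double-stranded RNA. Of 26 NF-kB and inflammatory genes 8 rose and 2 fell (adjusted p = 0.18), among them the cytokine genes LIF (1.02 ± 0.057) and IL32 (1.497 ± 0.15). Among 27 unfolded protein and integrated stress response genes 11 rose and 13 fell (adjusted p = 0.18). ATF4, the central transcription factor of the integrated stress response, fell from 485 ± 4.54 to 244 ± 7.26 CPM along with SLC7A11. Of 24 cholesterol synthesis genes 12 rose and 7 fell (adjusted p = 0.788), with a fall of HMGCS1 (-0.48 ± 0.042). Lysosome and autophagy genes rose in 20 of 29 cases and fell in 4 (adjusted p = 0.00789, and adjusted p = 0.183 with an estimated correlation). The lysosomal enzyme genes NEU1 (1.04 ± 0.057) and CTSA (0.48 ± 0.048) were among the rises. Of 28 MYC and ribosome biogenesis genes 3 rose and 11 fell (adjusted p = 0.18), with falls of UTP20 (-0.73 ± 0.064) and NCL (-0.36 ± 0.034). Adjusted over the list alone, 17 cell death genes rose, 1 inflammatory gene fell and 10 ribosome biogenesis genes fell, and the other counts of this paragraph were the same.

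Gastric and intestinal epithelial genes rose in 15 of 31 cases in AGS and fell in 3 (adjusted p = 0.000386, and adjusted p = 0.0758 with an estimated correlation). MUC13 rose by 2.94 ± 0.065 and the keratin gene KRT7 by 3.12 ± 0.12. Of 19 epithelial-mesenchymal transition genes 7 rose and 3 fell (adjusted p = 0.184), with rises of the matricellular genes CTGF (2.45 ± 0.066) and CYR61 (1.05 ± 0.061). All 13 mitochondrially encoded mRNAs rose (adjusted p = 1.22e-05, and adjusted p = 0.066 with an estimated correlation), MT-ND4 by 0.52 ± 0.033 and MT-CYB by 0.57 ± 0.038, and the share of mitochondrial rRNA in all counts was 0.388% ± 0.003 untreated and 0.57% ± 0.045 treated (SD, n = 3). Squamous keratinocyte markers rose in 12 of 17 cases, and the other 5 did not pass (adjusted p = 5.53e-08, and adjusted p = 0.066 with an estimated correlation). SERPINB5 rose from 79.7 ± 1.99 to 245 ± 19.8 CPM and LY6D from 1.08 ± 0.1695 to 15.1 ± 3.32 CPM, while the basal keratin genes KRT5 and KRT14, list members named for a test of keratinocyte RNA, stood at 0.236 and 4.02 CPM in treated AGS. Of 4 fibroblast and endothelial markers tested, COL5A1 (3.30 ± 0.18) and COL1A1 (1.03 ± 0.096) rose (adjusted p = 0.03, and adjusted p = 0.0955 with an estimated correlation). That call also ended with DESeq2 (0.0562), the replicate block (0.063) and the GC content offset (0.0671), and without untreated AGS replicate 1 (0.0529). Of 4 blood cell markers tested, CSF1R rose to 2.2 ± 0.332 CPM by 2.54 ± 0.41 (3.34 without untreated AGS replicate 1) and LYZ fell by 0.19 ± 0.077 (adjusted p = 0.706 for the list). The LYZ call ended without untreated AGS replicate 1 (0.173) or 2 (0.0821), and without treated AGS replicate 1 (0.109) or 2 (0.0789). It also ended without a low-count filter (0.0805), with the replicate block (0.0589) and with the GC content offset, where LYZ stood at -0.007 (0.963). Adjusted over the list alone, the counts of this paragraph were the same. In AGS the calls of the p53, interferon and histone lists held with an estimated correlation (adjusted p = 0.00164, 0.0298 and 0.0303). Across 13593 protein-coding genes, which are not independent replicates, AGS log2 fold changes had a Spearman's rho of 0.367 with transcript GC content and -0.252 with genomic length. With the GC content offset, chosen after seeing the data, 4726 genes rose and 4257 fell, 3855 and 3426 of them called in the same direction in both fits.

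**Figure D2:**
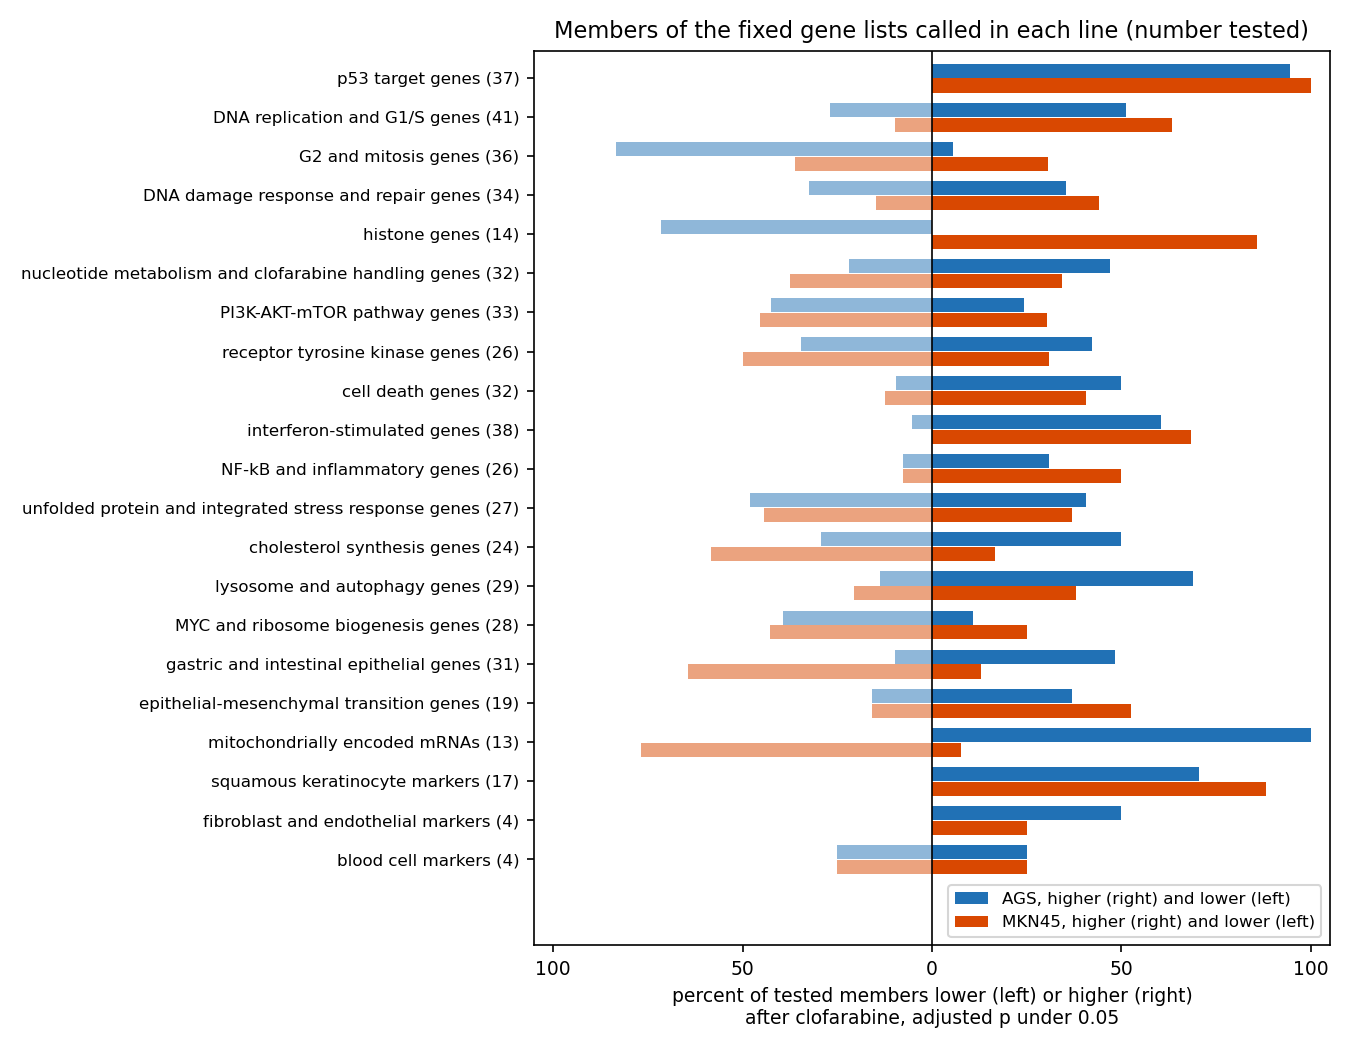
Percent of the tested members of each of the 21 gene lists that were lower (left, pale bars) or higher (right, solid bars) after clofarabine in AGS (blue) and MKN45 (orange), at an adjusted p under 0.05, with the number of members tested in brackets. The p53 list stands at 35 of 37 genes higher in AGS and 37 of 37 in MKN45, and the histone and mitochondrial lists point in opposite directions in the 2 lines.

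The comparison in MKN45 asked the same question in the other line. The p53 targets rose here too, together with interferon-stimulated genes, while genes of the gastric and intestinal epithelium fell, a list call that ended with an estimated correlation (adjusted p = 0.0889). MDM2 rose from 530 ± 32.04 to 2976 ± 124 CPM, a log2 fold change of 2.49 ± 0.041 (SE, n = 3), and CDKN1A from 327 ± 19.5 to 2259 ± 79.4 CPM. The stress-responsive transcription factor gene ATF3 rose from 34.9 ± 3.16 to 413 ± 3.298 CPM and RRM2B from 66.7 ± 2.35 to 327 ± 17.4 CPM. MYC fell from 62.6 ± 5.296 to 25.9 ± 1.35 CPM and PIK3R1 from 154 ± 3.69 to 70.9 ± 1.86 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4336 genes rose and 4293 fell, 1047 and 266 of them by a log2 fold change of at least 1.

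The largest rises in MKN45 again began from low levels. SORCS3, a sorting receptor, rose to 7.15 ± 0.235 CPM by 6.20 ± 0.42, or by 7.78 and 5.50 without untreated MKN45 replicate 2 or 3. LCE1E, a gene of the cornified envelope of skin, rose by 5.56 ± 0.30, and ABCA12, the lipid transporter of keratinocytes, from 1.77 ± 0.476 to 47.8 ± 2.48 CPM. NTNG2 rose by 4.88 ± 0.37 (5.56 without untreated MKN45 replicate 3) and RRAD, a small GTPase and known p53 target, by 4.26 ± 0.29 (4.86 without untreated MKN45 replicate 2). TMEM40 rose by 4.62 ± 0.27. Most of these genes also rose in AGS: LCE1E by 6.29 ± 0.60, SORCS3 by 4.73 ± 0.86, TMEM40 by 4.71 ± 0.32, RRAD by 4.50 ± 0.35 and ABCA12 by 4.25 ± 0.12. NTNG2 did not pass there. The largest falls were smaller: the mitochondrial histidine tRNA MT-TH (-1.96 ± 0.21), ZBTB12 (-1.85 ± 0.19), the inhibitory SMAD gene SMAD6 (-1.53 ± 0.081), the chemokine CXCL1 (-1.51 ± 0.36) and the transcription factors TWIST1 (-1.51 ± 0.20) and MYB (-1.48 ± 0.10).

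All 37 p53 target genes rose in MKN45, with a median log2 fold change of 1.69. Camera's adjusted p was 4.24e-155 at the preset correlation, and 4.38e-05 with an estimated correlation. BTG2 rose by 2.42 ± 0.046, CDKN1A by 2.79 ± 0.043 and GDF15 by 1.07 ± 0.089. CDKN1A (ENSG00000124762) lies on chromosome 6 from 36676460 to 36687339 on the forward strand, and MDM2 (ENSG00000135679) on chromosome 12 from 68808176 to 68850686 on the forward strand. Of 41 DNA replication and G1/S genes, 26 rose and 4 fell (adjusted p = 0.00167, and adjusted p = 0.115 with an estimated correlation). PCNA, the DNA polymerase clamp, rose by 0.63 ± 0.037 and the transcription factor gene E2F1 by 0.65 ± 0.057. Among 36 G2 and mitosis genes 11 rose and 13 fell (adjusted p = 0.401), and the median was above 0 while the mean and the test pointed down. PLK1 and CDC20, which drive mitotic entry and exit, fell by 0.98 ± 0.046 and 0.64 ± 0.042. Of 34 DNA damage response and repair genes 15 rose and 5 fell (adjusted p = 0.0896). That p lay between 0.0229 and 0.0493 without untreated MKN45 replicate 1 or 2 or treated MKN45 replicate 1 or 2, and was 0.042 with the replicate block and 0.000844 without a low-count filter. The nuclease gene EXO1 rose by 0.94 ± 0.072 and BRCA1 by 0.63 ± 0.057. Histone genes rose in 12 of 14 cases, and the other 2 did not pass (adjusted p = 0.00257, and adjusted p = 0.0663 with an estimated correlation). H1F0 rose by 0.70 ± 0.044 and HIST1H2BC by 1.51 ± 0.17, while small nuclear and nucleolar RNAs stood at 77.4 ± 1.53 CPM untreated and 76.1 ± 2.42 CPM treated. Adjusted over the list alone, 27 replication genes rose, 12 mitosis genes rose and 14 fell, 16 repair genes rose, and the other counts of this paragraph were the same.

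Among 32 nucleotide metabolism and clofarabine handling genes in MKN45, 11 rose and 12 fell (adjusted p = 0.167), with a median below 0 and a mean and test above it. RRM2B (ENSG00000048392, chromosome 8 from 102204502 to 102239118 on the reverse strand) rose by 2.30 ± 0.047, PNP by 0.84 ± 0.044, RRM2 by 0.62 ± 0.045 and RRM1 by 0.32 ± 0.045. DCK fell by 0.34 ± 0.068 and SLC29A1 by 0.46 ± 0.049. Of 33 PI3K-AKT-mTOR pathway genes 10 rose and 15 fell (adjusted p = 0.329), with a median above 0 and a mean and test below it. PIK3R1 fell by 1.12 ± 0.050 and INPP5D rose by 2.32 ± 0.097, while PIK3CA had a log2 fold change of 0.097 ± 0.081 (adjusted p = 0.334). Of 26 receptor tyrosine kinase genes 8 rose and 13 fell (adjusted p = 0.64), with a median and test below 0 and a mean above it. AXL rose by 3.09 ± 0.14, FGFR4 fell by 0.97 ± 0.055, MET fell by 0.31 ± 0.035, and EGFR had a log2 fold change of -0.037 ± 0.049 (adjusted p = 0.554). The counts were the same when adjusted over the list alone, except that 13 nucleotide metabolism genes fell.

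Of 32 cell death genes 13 rose and 4 fell in MKN45 (adjusted p = 0.00555, and adjusted p = 0.158 with an estimated correlation). PMAIP1, which encodes the pro-apoptotic NOXA, rose by 1.72 ± 0.073, and its anti-apoptotic partner MCL1 by 0.56 ± 0.036. Interferon-stimulated genes rose in 26 of 38 cases, and the other 12 did not pass (adjusted p = 4.03e-16). IFIT2 rose from 103 ± 3.65 to 352 ± 12.8 CPM and IFIT3 from 39.8 ± 3.601 to 151 ± 4.11 CPM, both effectors against viral RNA. Of 26 NF-kB and inflammatory genes 13 rose and 2 fell (adjusted p = 0.00555, and adjusted p = 0.512 with an estimated correlation), with rises of the prostaglandin synthase gene PTGS2 (1.05 ± 0.050) and of LIF (1.02 ± 0.052). Among 27 unfolded protein and integrated stress response genes 10 rose and 12 fell (adjusted p = 0.482), with a median below 0 and a mean and test above it. ATF3 (ENSG00000162772, chromosome 1 from 212565334 to 212620777 on the forward strand) rose by 3.57 ± 0.072, and the chaperone gene HSPA5 fell by 0.50 ± 0.034. Cholesterol synthesis genes fell in 14 of 24 cases and rose in 4 (adjusted p = 0.00555, and adjusted p = 0.208 with an estimated correlation). HMGCS1, an early enzyme of the pathway, was among the rises (0.86 ± 0.045). Of 29 lysosome and autophagy genes 11 rose and 6 fell (adjusted p = 0.115), with rises of the autophagosome genes MAP1LC3B (0.94 ± 0.057) and GABARAPL1 (0.99 ± 0.067). Of 28 MYC and ribosome biogenesis genes 7 rose and 12 fell (adjusted p = 0.0723, and 0.0299 and 0.0437 without untreated or treated MKN45 replicate 1). MYC fell by 1.27 ± 0.063 and RRP12 rose by 1.21 ± 0.042. The counts of this paragraph adjusted over the list alone were the same, except that 14 ribosome biogenesis genes fell.

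Gastric and intestinal epithelial genes fell in 20 of 31 cases in MKN45 and rose in 4 (adjusted p = 0.000351, and adjusted p = 0.0889 with an estimated correlation). VIL1, the actin-bundling protein villin of the brush border, fell by 0.71 ± 0.037, whereas MUC13 rose by 0.92 ± 0.059. Of 19 epithelial-mesenchymal transition genes 10 rose and 3 fell (adjusted p = 0.00555, and adjusted p = 0.274 with an estimated correlation). ACTA2, smooth muscle actin and also a p53-responsive gene, rose by 3.55 ± 0.19 and the transcription factor gene SNAI2 by 2.63 ± 0.19. Mitochondrially encoded mRNAs fell in 10 of 13 cases and rose in 1 (adjusted p = 0.0002, and adjusted p = 0.113 with an estimated correlation). MT-ND3 fell by 0.68 ± 0.040 and MT-CYB by 0.47 ± 0.038, while mitochondrial rRNA took 0.487% ± 0.018 of counts untreated and 0.849% ± 0.05 treated (SD, n = 3). Squamous keratinocyte markers rose in 15 of 17 cases, and the other 2 did not pass (adjusted p = 1.32e-12). KRT15 rose from 16 ± 1.18 to 57.3 ± 0.5003 CPM and SPRR1B from 11.7 ± 0.669 to 41.2 ± 0.757 CPM, with KRT5 and KRT14 at 25.8 and 5.26 CPM in treated MKN45. Of 4 fibroblast and endothelial markers tested COL1A1 rose by 1.42 ± 0.15 (adjusted p = 0.441 for the list). Of 4 blood cell markers tested HBB rose to 1.94 ± 0.376 CPM and LYZ fell by 0.18 ± 0.066 (adjusted p = 0.887 for the list). The LYZ call ended without untreated MKN45 replicate 3 (0.156) and without treated MKN45 replicate 1 (0.074) or 3 (0.0799), and without a low-count filter (0.0559). Adjusted over the list alone, the counts of this paragraph were the same. In MKN45 the calls of the p53, interferon and keratinocyte lists held with an estimated correlation (adjusted p = 4.38e-05, 0.00139 and 0.0358). MKN45 log2 fold changes had a Spearman's rho of -0.017 with transcript GC content across the protein-coding genes.

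Genes called in both lines more often moved in the same direction than in opposite ones. Both lines raised 2022 genes and lowered 1997, where independent lists of these sizes would share 1223 and 1162. A further 804 genes rose in AGS and fell in MKN45, and 823 did the reverse, against 1211 and 1173 for independent lists. Of the 5646 genes called in both lines 71.2% had the same sign. CDKN1A, MDM2, RRM2B, AXL and ATF3 rose in both, and PIK3R1, PLK1 and CDC20 fell in both. The log2 fold changes of the lines had a Spearman's rho of 0.302 and a Pearson's r of 0.342 across 16893 genes, which are not independent replicates. That rho was lower without a low-count filter, as given with the alternatives below. The lines have separate untreated libraries, so no shared control adds to these values.

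**Figure D3:**
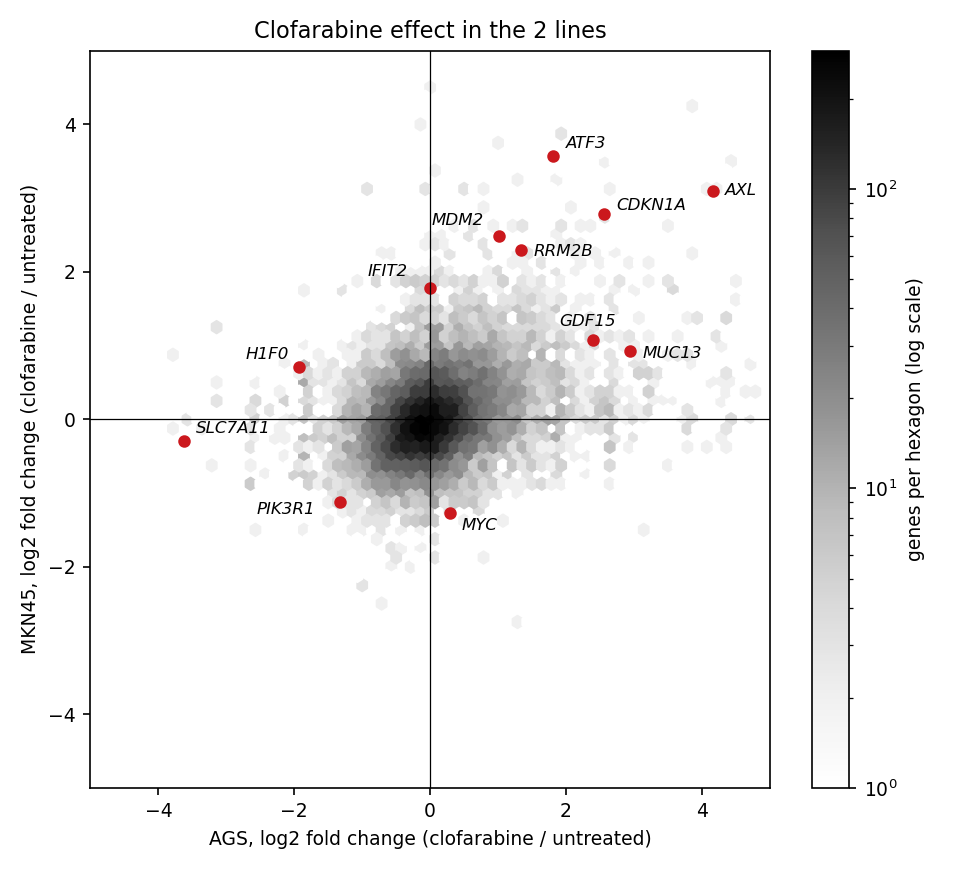
Log2 fold change after clofarabine in AGS (horizontal) against MKN45 (vertical) for 16814 genes, with shading for the number of genes per hexagon on a log scale and 12 genes marked in red. The 79 genes beyond 5 on either axis are left out, CDKN1A, AXL and ATF3 lie high in both lines, and H1F0 and MYC lie in opposite quadrants.

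The effects of the lines were then compared with each other, as AGS minus MKN45. Histone genes had lower log2 fold changes in AGS than in MKN45, and gastric epithelial genes and mitochondrial mRNAs higher ones. Mitosis genes and, in 19 of 37 cases against 11, p53 targets were also lower, list calls that ended with an estimated correlation (adjusted p = 0.187 and 0.357). KRT7 rose in AGS and fell in MKN45, a difference of 3.46 ± 0.13 (SE, n = 3 per group), and MYC, up by 0.29 ± 0.052 in AGS, differed by 1.56 ± 0.081. H1F0 differed by -2.63 ± 0.060 and SLC7A11, whose fall in MKN45 was -0.30 ± 0.047, by -3.33 ± 0.085. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the effect was higher in AGS for 3748 genes and lower for 3503. Of the genes raised in both lines 894 still differed in size, as did 709 of those lowered in both. Line and medium were confounded, so the difference belongs to the pair of line and medium.

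Gastric and intestinal epithelial genes had a higher effect in AGS for 18 of 31 members, and the other 13 did not pass (adjusted p = 3.72e-12). The same held for all 13 mitochondrial mRNAs (adjusted p = 1.52e-15), with MT-CYB at 1.04 ± 0.054. Histone genes had a lower effect in AGS in 12 of 14 cases, and the other 2 did not pass (adjusted p = 4.5e-11). These calls of the gastric, mitochondrial and histone lists held with an estimated correlation (adjusted p = 0.00557 for each). Mitosis genes were lower in 29 of 36 cases and higher in 2 (adjusted p = 3.53e-11, and adjusted p = 0.187 with an estimated correlation). Of the p53 targets 11 were higher and 19 lower in AGS (adjusted p = 0.00342, and adjusted p = 0.357 with an estimated correlation), with CDKN1A at -0.23 ± 0.058, MDM2 at -1.48 ± 0.056 and GDF15 at 1.32 ± 0.13. Cholesterol synthesis genes were higher in 14 of 24 cases and lower in 2 (adjusted p = 0.0093, and adjusted p = 0.323 with an estimated correlation). Stress response genes were higher in 8 of 27 cases and lower in 13 (adjusted p = 0.00638, and adjusted p = 0.187 with an estimated correlation), a call that ended without treated AGS replicate 1 or any 1 MKN45 library (0.0523 to 0.113), without a low-count filter (0.0666) and with the replicate block (0.0658). Receptor tyrosine kinase genes were higher in 10 of 26 cases and lower in 5 (adjusted p = 0.0471, and adjusted p = 0.353 with an estimated correlation). That call ended with DESeq2 size factors (0.0518), no low-count filter (0.108), the stricter filter (0.0594), the replicate block (0.122) and the GC content offset (0.43). It also ended without each of 11 of the 12 libraries, the exception being untreated AGS replicate 2 (range 0.0417 to 0.145). When adjusted over the list alone, 20 p53 targets were lower, 3 mitosis genes and 19 gastric genes were higher, 6 receptor genes were lower, and the other counts of this paragraph were the same.

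The remaining lists did not differ past the threshold. Their adjusted p was 0.287 for replication, 0.09 for repair, 0.121 each for nucleotide metabolism, interferon-stimulated and keratinocyte genes, 0.641 for PI3K, where median and test differed in sign, and 0.54 for cell death. It was 0.621 for NF-kB, 0.301 each for lysosome and epithelial-mesenchymal transition genes, 0.677 for ribosome biogenesis, 0.305 for fibroblast and 0.719 for blood markers. The repair value fell to 0.0441 without treated AGS replicate 3 and to 0.044 without untreated MKN45 replicate 1, and the nucleotide value to 0.0477 with the GC content offset. Without a low-count filter they were 0.0135 and 0.00303, and that of lysosome genes 0.0457. Within those lists RRM2B differed by -0.96 ± 0.066, RRM2 by 0.37 ± 0.061, DCK by 0.33 ± 0.090, SLC29A1 by 1.00 ± 0.074 and PIK3CA by -0.65 ± 0.12. RRM1 (0.13 ± 0.061, adjusted p = 0.0884), EGFR (0.055 ± 0.070, 0.566) and MET (-0.10 ± 0.057, 0.163) did not pass. The RRM1 value passed with the GC content offset (0.27, adjusted p = 1.61e-05) and without untreated or treated MKN45 replicate 3 (0.0277 and 0.0358), and that of MET without treated AGS replicate 3 (0.0325). PIK3R1 differed by -0.20 ± 0.071 (adjusted p = 0.0168), but by 0.021 (0.832) with the GC content offset and by -0.14 (0.123) without treated AGS replicate 2.

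The largest differences between the effects came from genes near 0 in 1 line. UNC13A differed by 6.96 ± 0.35 (8.49 without untreated AGS replicate 1) and HTRA3 by -7.90 ± 0.64 (-9.51 and -7.20 without untreated MKN45 replicate 1 or 3). NTNG2 differed by -5.36 ± 1.60, a value that moved to -8.003 without treated AGS replicate 3, to -6.03 without untreated MKN45 replicate 3, and to -4.73 (adjusted p = 0.131) without untreated AGS replicate 1. ZNF559 went from 0 counts in untreated AGS to 1.27 ± 0.363 CPM, at least 25.4-fold higher, and stood at 12.8 ± 1.73 CPM in untreated MKN45. CBS, NPNT and TENM4 also had 0 counts in untreated AGS and were at least 9.18-, 7.26- and 3.63-fold higher after treatment. Their treated levels were 0.461 ± 0.144, 0.364 ± 0.257 and 0.182 ± 0.108 CPM. The NPNT difference, which rests on 0 counts in 1 group, moved from 5.85 to 5.22 without treated AGS replicate 2. The treated AGS level was 9.44% of the untreated MKN45 level for ZNF559, 2.31% for CBS and 0.188% for NPNT. Such percents use pooled counts and library totals without TMM scaling, so they differ slightly from ratios of the CPM values. In MKN45, IRAK3 had 0 counts untreated and reached 0.162 CPM, at least 2.97-fold higher. SPP1 also had 0 counts in untreated MKN45, and its 0.142 CPM after treatment, 0.286% of the AGS level, did not pass (adjusted p = 0.11). PPP1R3G stood at 0.228 ± 0.198 CPM in untreated AGS and had 0 counts after treatment, and it rose by 1.49 ± 0.26 in MKN45. Its bound in AGS was 4.42-fold lower by the untreated mean, but treated and untreated AGS libraries overlapped.

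The untreated lines were compared as a background to the treatment effects. MKN45 expressed more gastric and intestinal epithelial genes, and AGS more cholesterol synthesis genes. MET, the hepatocyte growth factor receptor, stood at 3860 ± 52.03 CPM in MKN45 and 76.1 ± 4.401 CPM in AGS (SD, n = 3), a log2 difference of -5.67 ± 0.045 for AGS minus MKN45. MDM2 (-1.27 ± 0.041), CDKN1A (-0.47 ± 0.042), GDF15 (-1.87 ± 0.094), SLC29A1 (-1.90 ± 0.053) and EGFR (-0.41 ± 0.049) were also lower in AGS. RRM1 (1.51 ± 0.044), DCK (0.82 ± 0.063) and RRM2 (0.62 ± 0.045) were higher in AGS. RRM2B (0.29 ± 0.050) and PIK3CA (0.28 ± 0.080) were higher too, but not with the GC content offset (0.067 and 0.083, adjusted p = 0.139 and 0.314). PIK3R1, at 0.19 ± 0.047, turned to -0.026 (0.559) with that offset. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 6591 genes were higher and 7092 lower in AGS, and line and medium were confounded here as well.

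Cholesterol synthesis genes were higher in AGS in 19 of 24 cases and lower in 5 (adjusted p = 2.05e-06), and gastric genes lower in 23 of 31 cases and higher in 5 (adjusted p = 1.48e-11). These list calls held with an estimated correlation (adjusted p = 0.0432 for each). Higher in AGS were also the lists of mitosis (31 of 36 genes higher and 3 lower, adjusted p = 0.000562, and adjusted p = 0.611 with an estimated correlation) and of replication (31 of 41 higher and 5 lower, 0.0117, and adjusted p = 0.504 with an estimated correlation). Repair genes were higher (22 of 34, with 10 lower, adjusted p = 0.0167, and adjusted p = 0.731 with an estimated correlation), as were epithelial-mesenchymal transition genes (12 of 19, with 6 lower, adjusted p = 0.034, and adjusted p = 0.611 with an estimated correlation), whose mean was below 0. That last call also ended with DESeq2 (0.0619), with only the groups compared (0.131) and with the replicate block (0.0796). Interferon-stimulated genes were lower in AGS in 23 of 38 cases and higher in 11 (adjusted p = 0.034, but 0.0516 with only the groups compared, and adjusted p = 0.464 with an estimated correlation). Keratinocyte markers were lower in 12 of 17 cases and higher in 4 (adjusted p = 0.00999, and adjusted p = 0.611 with an estimated correlation). The other lists had adjusted p of 0.147 for p53 targets, 0.849 for histones and for cell death, 0.479 for nucleotide metabolism, 0.774 for PI3K and for receptor kinases, and 0.394 for NF-kB and for ribosome biogenesis. They were 0.817 for the stress response, 0.957 for lysosome genes, where the mean lay below 0 and the test pointed up, 0.378 for mitochondrial mRNAs, 0.978 for fibroblast and 0.503 for blood markers. The counts given in this paragraph were the same adjusted over the list alone.

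Genes found in only 1 line made up the largest differences. PASD1, a cancer-testis gene, SEMA5A, the splicing factor gene LUC7L, ZNF595 and SPP1 had 0 counts in untreated MKN45 and were at least 1490-, 1430-, 1140-, 983- and 934-fold higher in AGS, where LUC7L stood at 62.3 ± 1.14 CPM. PPP1R1B, the phosphatase inhibitor DARPP-32, stood at 289.6 ± 15.5 CPM in untreated MKN45 and 0 counts in untreated AGS, at least 5770-fold lower. CMBL and NPNT were each at least 3560-fold lower in AGS, ERN2, the epithelial stress sensor IRE1 beta, at least 1960-fold and EMB at least 1790-fold. After treatment AGS held 0.239 CPM of CMBL and 0.157 CPM of ERN2. By pooled counts and library totals without TMM scaling, these were 0.122% and 0.154% of the untreated MKN45 level. PPP1R1B stood at 0.035 ± 0.0312 CPM and EMB at 0 CPM in treated AGS.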

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

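The results below were singled out because the clofarabine effect differed between the lines in the test of the difference itself. Of the tests in this part, those that compare transcripts nearly absent from 1 line with a common ratio to the other line were chosen after the result was seen. For the keratinocyte and long-gene tests the pattern had been seen, and the bounds were written before the test values were. The real grouping gave 7251 genes whose effect differed between the lines, against at most 2932 in the other splits, and 1 of 100 splits gave as many. The other splits mix treated with untreated libraries, so they remove the treatment effect itself in at least 1 line. They cannot show what equal effects in the lines would give, so no conclusion on chance is drawn for that count. For the count of genes called in AGS (9337, highest other split 1), in MKN45 (8629, highest other split 0) and between the untreated lines (13683, highest other split 0), the 10 splits of 6 libraries are too few for a share under 0.05.

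For 8 of the 21 lists the effect differed by camera's adjusted p: 0.00342 for p53 targets, 3.53e-11 for mitosis genes, 4.5e-11 for histones, 0.0471 for receptor tyrosine kinases, 0.00638 for the stress response, 0.0093 for cholesterol synthesis, 3.72e-12 for gastric genes and 1.52e-15 for mitochondrial mRNAs. With an estimated correlation the calls of p53 targets (0.357), mitosis genes (0.187), receptor kinases (0.353), the stress response (0.187) and cholesterol synthesis (0.323) ended, and those of histones, gastric genes and mitochondrial mRNAs held. The receptor kinase call ended without each of 11 of the 12 libraries, the exception being untreated AGS replicate 2 (range 0.0417 to 0.145), and the stress response call without treated AGS replicate 1 or any 1 MKN45 library (0.0523 to 0.113). Of the genes reported for the treatment comparisons or for the difference between them 80 differed. Among these ZNF559, CBS, TENM4, NPNT, PPP1R3G and IRAK3 were picked as the largest differences, so their passing follows from the choice. Most of the others were picked for their change within a line, so the count does not stand for genes at large. With a group at 0 counts in every library, SPP1, ZNF559, CBS, TENM4, NPNT, PPP1R3G and IRAK3 differed at adjusted p of 0.00483, 3.26e-10, 6.58e-06, 0.000153, 7.53e-06, 2.14e-05 and 0.000753 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

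For the other genes the difference is the AGS minus the MKN45 log2 fold change. Among genes with the largest single-line changes it was 6.96 for UNC13A, 1.93 for PTAFR, 1.84 for DQX1, -7.90 for HTRA3, -3.33 for SLC7A11, -3.33 for AKR1C2, -2.70 for AKR1C1, -5.36 for NTNG2, 1.43 for MT-TH, 0.70 for ZBTB12, 0.84 for SMAD6 and 1.40 for MYB. Among p53 targets and cell death genes it was -0.22 for BTG2, -0.23 for CDKN1A, -1.48 for MDM2, 1.32 for GDF15, 0.50 for BAX, -1.29 for PMAIP1 and -0.42 for MCL1. In replication, mitosis and repair it was -0.86 for MCM6, 0.71 for CCNE1, -0.60 for E2F1, -1.07 for ASPM, -0.64 for CENPF, -0.18 for CDC20, -1.07 for WEE1, -0.31 for MSH6, -0.33 for EXO1 and -0.31 for BRCA1. For histones and nucleotide metabolism it was -2.63 for H1F0, -1.34 for HIST1H2BK, -2.26 for HIST1H2BC, -0.96 for RRM2B, 0.35 for PNP, 0.37 for RRM2, 0.33 for DCK and 1.00 for SLC29A1. In PI3K and receptor tyrosine kinase signalling it was -0.20 for PIK3R1, -0.65 for PIK3CA, -0.51 for INPP5D, 1.40 for FGFR2, 0.37 for FGFR4 and 1.07 for AXL. Interferon, inflammatory and stress response genes gave 2.09 for OAS1, 0.49 for OAS3, -1.79 for IFIT2, -1.61 for IFIT3, 0.74 for IL32, -1.31 for PTGS2, -0.86 for ATF4, -1.75 for ATF3 and 0.67 for HSPA5. Cholesterol, lysosome and ribosome biogenesis genes gave -1.34 for HMGCS1, 0.92 for CTSA, -0.76 for MAP1LC3B, -0.42 for GABARAPL1, -0.77 for UTP20, 0.24 for NCL, -1.25 for RRP12 and 1.56 for MYC. Epithelial, mesenchymal, mitochondrial and other marker genes gave 2.01 for MUC13, 3.46 for KRT7, 0.72 for VIL1, 1.22 for CTGF, -2.90 for ACTA2, 0.66 for MT-ND4, 1.04 for MT-CYB, 1.04 for MT-ND3, 0.94 for SERPINB5, 1.27 for LY6D, -1.28 for KRT15, 3.11 for COL5A1 and 1.86 for CSF1R. Leaving out 1 library moved UNC13A to 8.49 (untreated AGS replicate 1), HTRA3 to -9.51 and -7.20 (untreated MKN45 replicates 1 and 3) and NTNG2 to -8.003 (treated AGS replicate 3) and -6.03 (untreated MKN45 replicate 3). The calls of NTNG2 (-4.73, adjusted p = 0.131, without untreated AGS replicate 1) and PIK3R1 (-0.14, 0.123, without treated AGS replicate 2) ended.

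Squamous keratinocyte markers rose in both lines, although with an estimated correlation the list call held in MKN45 (adjusted p = 0.0358) and ended in AGS (0.066), and the labels' growth protocol also names EPC2, a line kept in keratinocyte medium. RNA or cells of such a culture, as the only source of the rises, would raise KRT5, KRT14 and KRT6A, the most abundant keratinocyte mRNAs. Together these would then rise by more CPM than SERPINB5 in each line. In AGS their summed rise was 19.7 CPM against 165 CPM for SERPINB5, a difference of -145 (SD 12.8), and in MKN45 102 against 166 CPM, a difference of -64.3 (SD 35.6). These values argue against keratinocyte RNA as the only source of the rises. SERPINB5 was already read in untreated AGS and may have risen in the gastric cells themselves, so a smaller admixture cannot be excluded. In MKN45 these keratins still rose by 102 CPM. TP63 stood at 0.017 CPM in treated AGS and 1.01 CPM in treated MKN45. A response of the gastric cells to clofarabine stays open as a hypothesis, and 17 of the 20 markers passed the count filter in these lines.

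Transcripts with at most 3 counts over the untreated AGS libraries and at least 10 CPM in untreated MKN45, 221 in number, were detected in treated AGS at a pooled 0.308% of the untreated MKN45 level, against 0.0493% in untreated AGS, where low counts had been the criterion. The 10 CPM bound and the ratios used library totals without TMM scaling. Reads carried over from MKN45 libraries would put every such gene at 1 common ratio. Replicates at 3 to 30 counts differed by a chi-square per degree of freedom of 1.75, so 95% intervals were widened from Poisson ones by that spread, a step added after the results were seen. Of these genes 9 (11 with Poisson intervals, which cover counting error only) had an interval wholly above 5 times the pooled ratio, led by TMCC3 (9.60%), ZNF559 (9.44%) and RIMS4 (9.33%), the first and last chosen after their values were seen. For these 9 genes carry-over at 1 ratio is argued against, and induction by clofarabine remains a candidate explanation. Of the other 212 genes 15.1% (Wilson 95% interval 10.9 to 20.5, and 24.1% with Poisson intervals) left out their pooled ratio of 0.196%, 23 above and 9 below it. With widened intervals that share lies between the 10% that 1 ratio allows and the 20% written as excluding it. Those bounds were written for Poisson intervals, whose share lies above 20%. The verdict thus rests on the choice of interval, and for these genes as a set carry-over and low transcription cannot be told apart. NPNT, CMBL and ERN2 had intervals that held the pooled ratio. PPP1R1B, named by the same rule, stood higher than those genes in untreated MKN45 (289.6 CPM) but lower in treated AGS (0.035 ± 0.0312 CPM). EMB, at 89.7 CPM in untreated MKN45, stood at 0 CPM in treated AGS, so both lay on the low side, at few or no counts. CBS, also among the 212 genes, stood at 2.31% (1.29 to 3.81), wholly above it. In MKN45 the reverse set of 49 genes stood at 0.158% of the AGS level treated and 0.0459% untreated, with 1 gene, CPNE7 (2.63%), above that limit, chosen after its value was seen.

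Long genes fell relative to short ones in treated AGS, with a median log2 fold change of 0.16 for spans under 5 kb and -0.29 over 200 kb, and Spearman's rho was -0.252 in AGS and -0.041 in MKN45. A fall of long genes in both lines with a rho below -0.1, the bound written for it, is argued against, since MKN45 missed it. With exonic length, transcript GC content and expression held fixed, the partial rho was -0.094 in AGS (-0.104 to -0.081 over treated libraries) and -0.08 in MKN45 (-0.084 to -0.069), and MKN45 genes over 200 kb had a median of -0.10 (36.1% lower, 18.6% higher). These partial values also missed -0.1, and they were close to each other in the 2 lines. Without the genes of the 21 lists rho in AGS was -0.256. As 13052 of 13593 genes were left, rho could hardly have moved to the -0.1 bound. This value therefore does not bear on the source of the AGS trend. The partial rho in AGS lay between the bounds set beforehand. Exonic length, GC content, expression and span therefore cannot be told apart as the source of the AGS trend. The deviation of each library's log2 CPM from the mean of its line's 6 libraries had a rho with GC content of -0.329, -0.311 and -0.33 in untreated and 0.399, 0.322 and 0.237 in treated AGS, while the MKN45 values ran from -0.154 to 0.173. Opposite signs between the groups of a line follow from this centring where a trend exists, so the values show its size and not which group departs. A library preparation that differed between the AGS groups and a loss of long transcripts under clofarabine both stay open, as the labels give no batch.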

How the results depend on the processing

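The GC content offset was chosen after the result was seen, and the other alternatives before the data were examined. Over the alternatives other than leaving out a library, named-gene results counted as kept in 1210 cases, lost the call in 64, gained it in 1 and turned in 3. Most of these losses came from the test against a log2 fold change of 1, which asks a different question. Under the other settings only LYZ, RRM2B and PIK3CA lost a call. A result called in neither fit counted as kept whatever its direction, so turns were counted only with a call in at least 1 fit. List results, those of the untreated lines included, counted as kept in 640 cases, lost the call in 41 and gained it in 54. Leaving out 1 library gave 1128 kept, 9 lost and 3 gained for genes, and 602, 19 and 9 for lists. Tested against a log2 fold change of 1, 791 genes rose and 117 fell in AGS, 425 and 12 in MKN45, 159 rose and 1 fell in both, and 0 and 1 moved in opposite directions (AGS higher, then lower), as this test asks for larger changes. Camera with an estimated correlation called 2 lists higher and 1 lower in AGS, 3 and 0 in MKN45, 2 and 1 for the difference, and 1 and 1 between the untreated lines. Fry, which does not compare a list with other genes, called 14 and 5, 13 and 5, 9 and 7, and 6 and 13 between the untreated lines. With camera at its preset correlation the counts were 9 and 2, 8 and 3, 4 and 4, and 5 and 3. Without a low-count filter 7 lists were lower between the untreated lines and Spearman's rho of the lines' fold changes was 0.126, and with only the groups compared it was 0.341, for which the cause was not tested. The GC content offset lowered the rho of AGS fold changes with GC content over all tested genes from 0.327 to 0.02, as its construction asks. With it DCK in AGS turned to 0.226, PIK3R1 to 0.021 in the difference and to -0.026 between the untreated lines. Whether it removed a technical trend or a treatment effect from these genes was not tested. The replicate numbers did not pair the libraries, with correlations of same-numbered deviations from -0.033 to 0.01 and no group pair in which every sample correlated best with its own number. With the number as a block 4605 genes rose and 4431 fell in AGS, 4174 and 4109 in MKN45, and 3563 and 3340 differed, and 1 of 168 named-gene calls changed, that of LYZ in AGS. The block ended the list calls of fibroblast markers in AGS (0.063) and of receptor kinases (0.122) and the stress response (0.0658) in the difference and of epithelial-mesenchymal transition genes between the untreated lines (0.0796), and added that of repair genes in MKN45 (0.042). Other list calls were added without a low-count filter for NF-kB (0.0461) and ribosome biogenesis genes (0.0388) in AGS and for lysosome (0.0253) and ribosome biogenesis genes (0.0438) in MKN45, with only the groups compared for NF-kB genes in AGS (0.00161) and with the GC content offset for ribosome biogenesis genes in AGS (0.0498). Between the untreated lines, no low-count filter added histones (0.0406), NF-kB (0.0114), ribosome biogenesis (0.0389), mitochondrial mRNAs (0.0114) and blood markers (0.0459), and the fit of only the groups compared added NF-kB (0.029). Leaving out 1 library gave 4399 to 4615 rises and 4169 to 4405 falls in AGS, 3951 to 4101 and 3905 to 4056 in MKN45, and 3442 to 3658 and 3271 to 3508 for the difference. At 15720654 to 27880776 counts per library, folds of genes with 0 counts in a group are known only as lower bounds, which leave out the error of the other group.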

Other observations

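Of the tests in this part, the one on neighbouring silent genes was chosen after the result was seen, and the list of cancer-testis genes was written after SPANXB1 was seen but before the list was tested. Several genes silent in 1 line lay side by side. The HOXA genes, which set position along the body axis, were read in MKN45 but hardly in AGS: HOXA10 stood at 25.2 ± 1.37 CPM and HOXA13 at 29.5 ± 2.54 CPM in untreated MKN45, each with 0 CPM in both AGS groups. HOXA13 fell by 1.01 ± 0.11 in treated MKN45. At the tip of chromosome 16, MPG, a DNA glycosylase gene, NPRL3, LUC7L and FAM234A stood at 17.7 ± 0.794, 35.9 ± 0.975, 62.3 ± 1.14 and 18.3 ± 0.988 CPM in untreated AGS and at 0 CPM in untreated MKN45. These genes were chosen after their values were seen.

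A hypothesis is that a block of neighbouring genes is missing or silenced in that line. Of 10500 genes expressed in AGS 50 had at most 3 counts in MKN45, and the longest run of neighbours was 4 genes (chromosome 16, 77007 to 268971 on GRCh38), against at most 3 in 10000 shuffles of gene order. Runs of 3 genes also held PSG1, PSG6 and PSG11 on chromosome 19 and SPANXC, MAGEC1 and MAGEC2 on chromosome X, families of similar genes that may be switched off together. Of 11198 genes expressed in MKN45 209 had at most 3 counts in AGS, with a longest run of 5 genes, HOXA5 to HOXA13 (chromosome 7, 27141052 to 27200106), against at most 4 in shuffles. The runs were seen before this comparison, and the shuffles break up clusters of genes regulated together, such as HOXA, so these values restate the observation and do not bear on the hypothesis. RNA counts do not tell a deletion from silencing.

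The hypothesis that cancer-testis genes rose beyond other genes of the same expression was tested because SPANXB1 was among the largest rises in AGS. In AGS 13 of 25 such genes rose and 3 fell, and the list's median log2 fold change of 0.48 lay at the 97.8 percentile of 10000 random lists matched on expression, just above their upper bound of 0.474. SPANXC rose from 0.442 ± 0.123 to 11.2 ± 2.99 CPM and PIWIL2, a germline gene, by 1.92 ± 0.31 in AGS and 1.07 ± 0.28 in MKN45, both chosen after their values were seen. In MKN45 4 of 19 rose and 2 fell, and the median of 0.073 lay at the 53.3 percentile, so a rise in both lines, which the hypothesis asked for, was not found.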
